A study of Arabidopsis thaliana with 3 samples.

How the data were processed

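Chromatin of seedlings carrying LDL1:GFP under the LDL1 promoter was precipitated with an anti-GFP antibody in 2 libraries, with 1 input library of the same line. Groups were taken from the sample titles. The deposited region coordinates (start and end on each chromosome, without a score or count) came as a set for the ChIP group and a set for the input, assigned to these groups by their names. Bowtie, SICER and the build TAIR10 are named per the submitters' processing notes, without version or role. Alignment settings, the treatment of reads with several matches and the threshold for a region are not given in the sources used here. Nor is it given whether the replicates were pooled or intersected, or whether only 1 was used. SICER joins windows of a fixed size, yet only 21 of the 5928 ChIP region widths were multiples of 200 bp, so the step that set the region edges is open. The input coordinates deposited by the authors behaved as merged reads rather than called regions, since they did not overlap each other, had a commonest width of 51 bp and covered 98.5% of the nuclear genome. They give presence of a read, not depth.

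All coordinates are 1-based on TAIR10. Gene names, gene positions and biotypes came from a RefSeq gene table for TAIR10.1, whose nuclear chromosomes are those of TAIR10. It was used for 37899 nuclear genes, of which 27444 are protein-coding. Chromosome length was taken as the end of the last input interval. Strand, exons and genome sequence were not used here. For that reason the planned class of 1 kb upstream became 1 kb on either side of a gene, UTR, exon and intron classes were not separated, and the planned tests of sequence motifs were not run.

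Region midpoints were assigned in order of precedence to within 1 kb outside a protein-coding gene, inside a protein-coding gene, inside a non-coding RNA gene, inside a pseudogene, or elsewhere. A gene was counted as holding a region when a region overlapped its body or the 1 kb on either side by at least 1 bp. Observed values were compared with 1000 random placements of regions of the same widths on the same chromosome. The two-sided permutation p has a smallest value of 0.002. Each region was placed independently, whereas some observed regions lie side by side. The SD of the placements can therefore be too small, and p-values for ratios close to 1 too low. Gene lists were compared with all other nuclear protein-coding genes by two-sided Fisher's exact test, with exact Clopper-Pearson intervals of 95% that cover counting error only. Genes are not independent replicates, and neighbouring genes can share a region. Values of p were adjusted by the Benjamini-Hochberg method over the classes and over the 11 lists, with a threshold of 0.05. Chromosome arms were compared by an exact paired permutation test over 10 arms.

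The tests, the 272 list members, the first set of alternatives and the rule for named genes were chosen before the data were examined. The rule takes the genes at the 20 widest regions (width, because the regions have no statistic of their own), up to 6 members with a region per list by region width, and CCA1, LHY, TOC1, GI, FLC, FT, SOC1, MAF4, MAF5, FWA and LDL1 whatever their result. Further list members with a region are also named where that completes a count, and these were chosen after their values were seen. All 272 members were found in the gene table. Gene-poor bins were defined after seeing the data as bins of 1 Mb with fewer than 150 protein-coding genes, and everything else was called arms.

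The alternatives were regions of at least the median width, gene bodies alone, an overlap of at least 200 bp, other orders and definitions of the position classes, placement within the same 1 Mb, stricter input overlap, and 10000 random gene sets matched on gene length. Added after seeing the data were midpoints within 1 kb of either gene end (in place of the planned gene start), the arms alone, gene sets matched on distance from the chromosome end or on the bin of 1 Mb, whole coverage by input, assignment of each region to its nearest gene only, and leaving out regions on a tRNA, snRNA or rRNA gene.

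The procedures were tested on simulated data. With lists of 30 genes in which regions were planted in 40% of members, the list test made a call in 89% of 100 simulations, and with 20% planted in 11%. Unchanged lists were called in 0.3% of 2000 cases. All other regions in these list simulations were placed at random on the same chromosome. Such placements reached 5728 genes, against 3350 observed, and lack the clustering of the observed regions. These rates therefore hold for that setting and not for the background of the data. Random placements treated as observed gave a p under the threshold in 6.5% of 200 cases. A count of regions by brute force matched for 200 of 200 genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.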

Results

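Chromatin immunoprecipitation followed by sequencing was used to map LDL1 in seedlings of Arabidopsis thaliana, ecotype Col-0, harvested at 14 days under long days. LDL1 is a plant homologue of the animal lysine-specific histone demethylase LSD1. The plants carried LDL1 fused to green fluorescent protein (GFP) under its own promoter, and chromatin was precipitated with an antibody against GFP. The series holds 3 libraries: 2 ChIP libraries described as biological replicates, and 1 input library of the same line. The data analysed here are a single set of ChIP regions, not separated by replicate, and a set of input intervals. The regions carry no score, fold enrichment or read count, so values have no replicate error and region width is the only measure by which regions could be ranked. The depth of the ChIP libraries is therefore unknown. The p-values below set the regions against random placements or other genes and say nothing about the spread between replicates.

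The first question was how much of the genome the LDL1:GFP regions occupied and how they related to the input. The ChIP set held 5928 regions on the 5 nuclear chromosomes, with a median width of 300 bp (interquartile range 241 to 411 bp). Together they covered 2.89 Mb, or 2.43% of the 119.1 Mb of nuclear sequence. Density was highest on chromosome 4, at 73.9 regions per Mb, and on chromosome 2, at 70.2 per Mb. It was 43.9 per Mb on chromosome 3, 43.1 on chromosome 5 and 32.2 on chromosome 1. Widths were strongly skewed: the 325 regions above 1 kb (5.48%) held 34.5% of all region bases, and the widest region spanned 33857 bp.

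The input intervals were stretches of sequence with at least 1 read, with a commonest width of 51 bp. They covered 98.5% of the nuclear genome. If reads fell at random, the 1.54% left uncovered would correspond to a mean depth of 4.17 reads per base. The number of intervals was 118593, against 150013 under that reading, so this depth is a rough figure. All 5928 ChIP regions overlapped an input interval, against 99.9% of random placements on the same chromosome (SD 0.0411 percentage points, two-sided permutation p = 0.00599), a measure close to its ceiling. ChIP regions were covered by input over their whole length in 76.8% of cases, against 68.4% ± 0.575 (SD, 1000 placements; permutation p = 0.002, the smallest that the placements can give). Regions can be called only where reads align, whereas placements also fell on sequence without aligned reads.

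The regions were concentrated around the centromeres. A set of 22 bins of 1 Mb with fewer than 150 protein-coding genes, chosen after the region density along the chromosomes had been seen, made up 18.5% of the genome and held 3429 regions (57.8%) and 70.2% of region bases. Random placement on the same chromosome put 1167 ± 30.6 regions there (SD, 1000 placements), a ratio of 2.94 (permutation p = 0.002, the smallest possible). Density was 156 regions per Mb in these gene-poor bins and 25.7 per Mb in the remaining chromosome arms. Regions above 1 kb were also more frequent there, at 8.40% of regions against 1.48% in the arms.

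**Figure D1:**
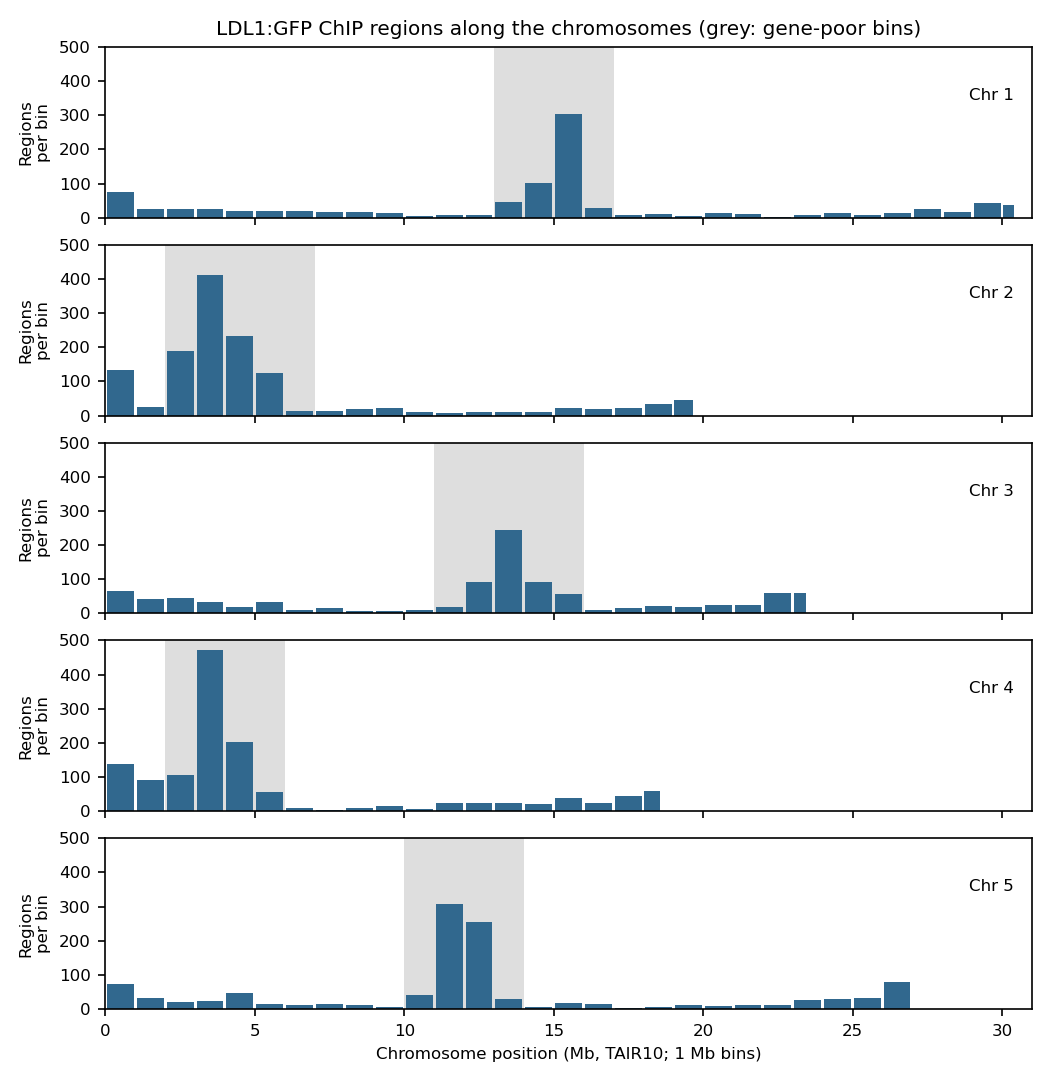
Number of LDL1:GFP ChIP regions (vertical axis) in bins of 1 Mb along chromosomes 1 to 5 (horizontal axis, Mb), with gene-poor bins shaded grey. The shaded bins hold 3429 of the 5928 regions, and the bin at 3 to 4 Mb of chromosome 2 holds 413.

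Of the 20 widest regions, 17 lay in gene-poor bins and 9 on chromosome 2. They ranged from 8002 to 33857 bp and together held 10.8% of all region bases. The widest block lay at 3 to 4 Mb of chromosome 2, where 6 of the 20 were found, among them chromosome 2: 3334870 to 3368726 and 3282039 to 3311470. This part of the chromosome carries a large insertion of mitochondrial DNA, which is close in sequence to the mitochondrial genome, so the origin of its reads is uncertain. The genes within 1 kb of these 6 regions included ABCI4 and a series of unnamed loci such as AT2G07689, AT2G07698 and AT2G07667. Another pair of wide regions covered ribosomal RNA genes: AT2G01010 and AT2G01020 under the region at 995 to 11569 of chromosome 2, next to the nucleolus organiser, and AT3G41768 and AT3G41979 under the region at 14191648 to 14208958 of chromosome 3. All 4 annotated nuclear rRNA genes held a region. On chromosome 4, regions of 20943 bp (3990856 to 4011798) and 18636 bp (3965434 to 3984069) had no protein-coding gene within 1 kb, as was true of 11 of the 20. Ribosomal RNA genes occur in many copies, so the position of a read among the copies is uncertain. For the wide regions without a protein-coding gene, copy number was not measured.

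Relative to genes, the picture depended on where the random placements were drawn. Over all regions, 31.2% of midpoints lay away from any annotated gene, against 17.1% ± 0.485 of random placements on the same chromosome, and 24.2% lay in a pseudogene, a class that in this annotation includes many transposon-derived loci, against 8.43% ± 0.365 (ratio 2.87). Protein-coding genes were under-represented, with 17.8% of midpoints inside a gene against 36.1% ± 0.644, and 26.1% within 1 kb of a gene against 37.8% ± 0.625 (SDs over 1000 placements; adjusted permutation p = 0.0025 for these 4 classes). Non-coding RNA genes held 0.709% of midpoints against 0.62% ± 0.0998 (adjusted permutation p = 0.402). By the order of precedence this leaves out midpoints inside or within 1 kb of a protein-coding gene. When gene bodies took precedence over the 1 kb flanks, the share was 2.41% against 1.35% ± 0.153 (ratio 1.78, adjusted permutation p = 0.002). With placement within the same 1 Mb, over the same regions, the class within 1 kb of a gene lay above the placements (24.3% ± 0.509, ratio 1.07, adjusted permutation p = 0.005). The class elsewhere no longer passed the threshold (30.2% ± 0.544, adjusted permutation p = 0.0649), the pseudogene ratio fell to 1.07, and the class inside protein-coding genes stayed below the placements (ratio 0.797). That class leaves out midpoints that also lie within 1 kb outside another gene. With placement within the same 1 Mb, 2108 protein-coding genes had their body overlapped, against 2055 ± 27.1 (ratio 1.03, adjusted permutation p = 0.0629). Counted as genes in the same way, also within the same 1 Mb, 942 pseudogenes were overlapped by a region, fewer than in placements (ratio 0.883). In the arms there were more than in placements (86 against 60.5 ± 6.80, ratio 1.42, adjusted permutation p = 0.0045 for both). Against placements on the same chromosome, the 942 pseudogenes were in excess (535 ± 20.7 in placements, ratio 1.76, adjusted permutation p = 0.0036).

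In the arms alone, with placements kept within the same 1 Mb, 54.9% of midpoints lay within 1 kb outside a protein-coding gene against 44.99% ± 0.982, and 6.202% lay elsewhere against 10.0% ± 0.587 (adjusted permutation p = 0.0025 for both). The share inside protein-coding genes, where midpoints within 1 kb outside another gene are not counted, was 34.3% against 42.0% ± 1.01. Counted as genes whose body was overlapped, the arms held 1821 against 1733 ± 24.7 in placements (ratio 1.05, adjusted permutation p = 0.00719). Within 250 bp of an end of a protein-coding gene lay 38.5% of arm regions, against 22.9% ± 0.812 (ratio 1.68; permutation p = 0.002, the smallest possible). Over all regions the share was 18.2%, above placements within the same 1 Mb (ratio 1.46, permutation p = 0.002) and below placements on the same chromosome (ratio 0.933, permutation p = 0.004). Starts and stops of genes were not told apart, because gene strand was not used here. The restriction to the arms was chosen after seeing the data.

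**Figure D2:**
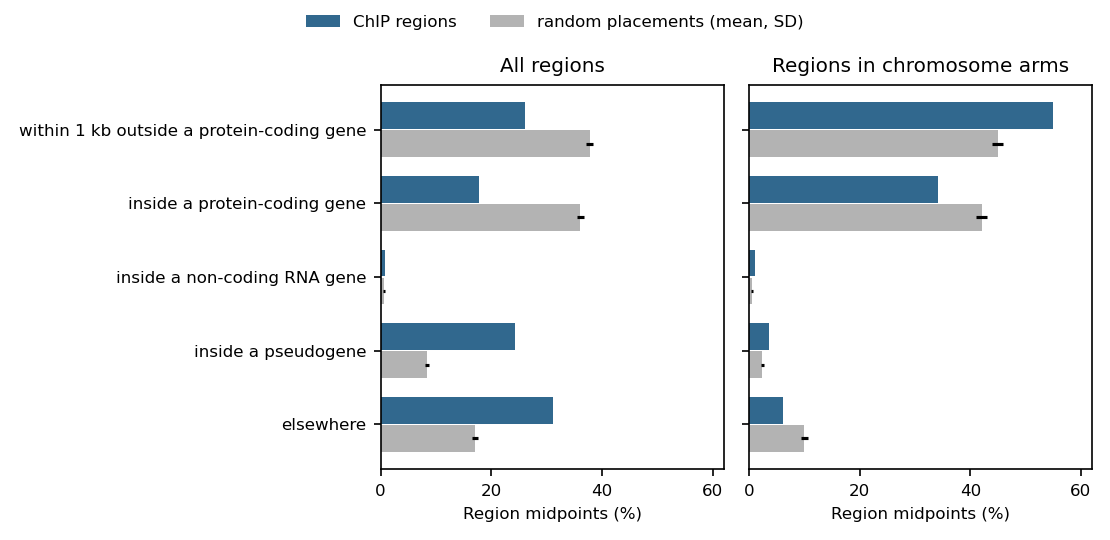
Percent of ChIP region midpoints (blue) and of random placements (grey, mean with SD over 1000 placements) in 5 classes of position, for all regions with placement on the same chromosome (left) and for arm regions with placement within the same 1 Mb (right). The class within 1 kb outside a protein-coding gene lies below the placements on the left (26.1% against 37.8%) and above them on the right (54.9% against 44.99%).

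LDL1:GFP regions overlapped or lay within 1 kb of 3350 of the 27444 nuclear protein-coding genes (12.2%). Random placement on the same chromosome reached 5728 ± 53.3 genes (ratio 0.585, permutation p = 0.002, the smallest possible). With each placement kept within the same 1 Mb the ratio was 0.987 (permutation p = 0.222), and in the arms alone it was 1.03 (permutation p = 0.00799). The last p can be too low for so slight a ratio, because regions were placed independently of each other.

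Within the arms, genes near the chromosome ends held regions far more often than genes farther in. In the outer 1 Mb of the 10 arms, 33.6% ± 5.21 of protein-coding genes held a region, against 11.003% ± 5.87 in the rest of the arm (SD, n = 10 arms), with a higher share in 10 of 10 arms (two-sided exact paired permutation p = 0.00195, the smallest possible). Regions per gene were 3.35 times as high in the outer 1 Mb (geometric mean over 10 arms, exact paired permutation p = 0.00391). The ratio was highest on the lower arm of chromosome 5, at 4.64, and was 0.99 on the upper arm of chromosome 4, the only arm not above 1. This comparison was chosen after the region density had been seen.

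**Figure D3:**
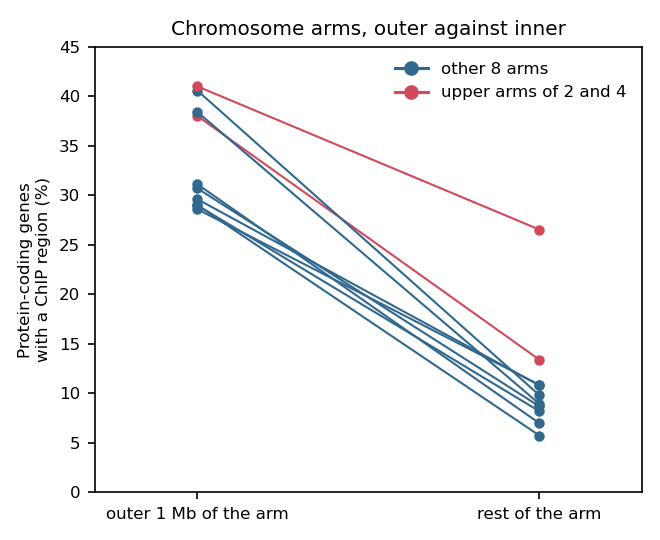
Percent of protein-coding genes with a ChIP region (vertical axis) in the outer 1 Mb and in the rest of each of 10 chromosome arms, joined by a line per arm, with the upper arms of chromosomes 2 and 4 in red. The outer share is higher in all 10 arms, with means of 33.6% and 11.003%.

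Because LDL1 has been linked to the circadian clock and to flowering, members of 11 gene lists fixed in advance were examined. Clock genes held LDL1:GFP regions more often than other genes: 10 of 28 members (35.7%, exact Clopper-Pearson 95% interval 18.6 to 55.9%) against 12.2% of other protein-coding genes, a ratio of 2.93 (Fisher's exact p = 0.00118, adjusted over 11 lists 0.013). LHY and CCA1, related MYB repressors expressed in the morning, held 5 and 2 regions. The widest at LHY was 670 bp (chromosome 1: 34467 to 35136) and at CCA1 325 bp (chromosome 2: 19248004 to 19248328), both overlapping the gene. TOC1, an evening-expressed repressor of CCA1 and LHY, held 4 regions, the widest of 508 bp (chromosome 5: 24674751 to 24675258). LHY and CCA1 lie 0.036 and 0.451 Mb from a chromosome end, in the outer 1 Mb where genes held regions more often. TOC1 lies 2.299 Mb from an end.

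Of the pseudo-response regulators that repress CCA1 and LHY during the day, PRR9 was overlapped by a region of 481 bp (chromosome 2: 19232244 to 19232724) and PRR7 lay 116 bp from a region of 492 bp (chromosome 5: 642147 to 642638) that contains a tRNA gene, AT5G02815. GI, which connects the clock to photoperiodic flowering, lay 640 bp from a region of 420 bp (chromosome 1: 8060691 to 8061110). ELF4, a component of the evening complex, was overlapped by a region of 344 bp and BOA, a homologue of the evening complex factor LUX, by a region of 356 bp. RVE1, a MYB-like factor related to CCA1, lay 70 bp from a region of 406 bp, and GRP7, a clock-regulated RNA-binding protein, lay 102 bp from a region of 319 bp that contains a tRNA gene, AT2G21670. In all, 6 of the 10 clock genes were overlapped and 4 lay beside a region. For 5 of the 10 the widest region also lay within 1 kb of another protein-coding gene, and at PRR7 and RVE1 it overlapped the body of that neighbour. The list missed the threshold with gene bodies alone (6 of 28, ratio 2.79, Fisher's exact adjusted p = 0.0973, the highest of 9 alternatives). The ratio was largest with regions of at least the median width (10 of 28 against 5.62% of other genes, ratio 6.35, Fisher's exact adjusted p = 1.83e-05, the lowest of the 9). The list also missed the threshold without the 102 regions on a tRNA, snRNA or rRNA gene, a test chosen after seeing the data, which left out PRR7 and GRP7 (8 of 28, ratio 2.46, Fisher's exact adjusted p = 0.0674).

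**Figure D4:**
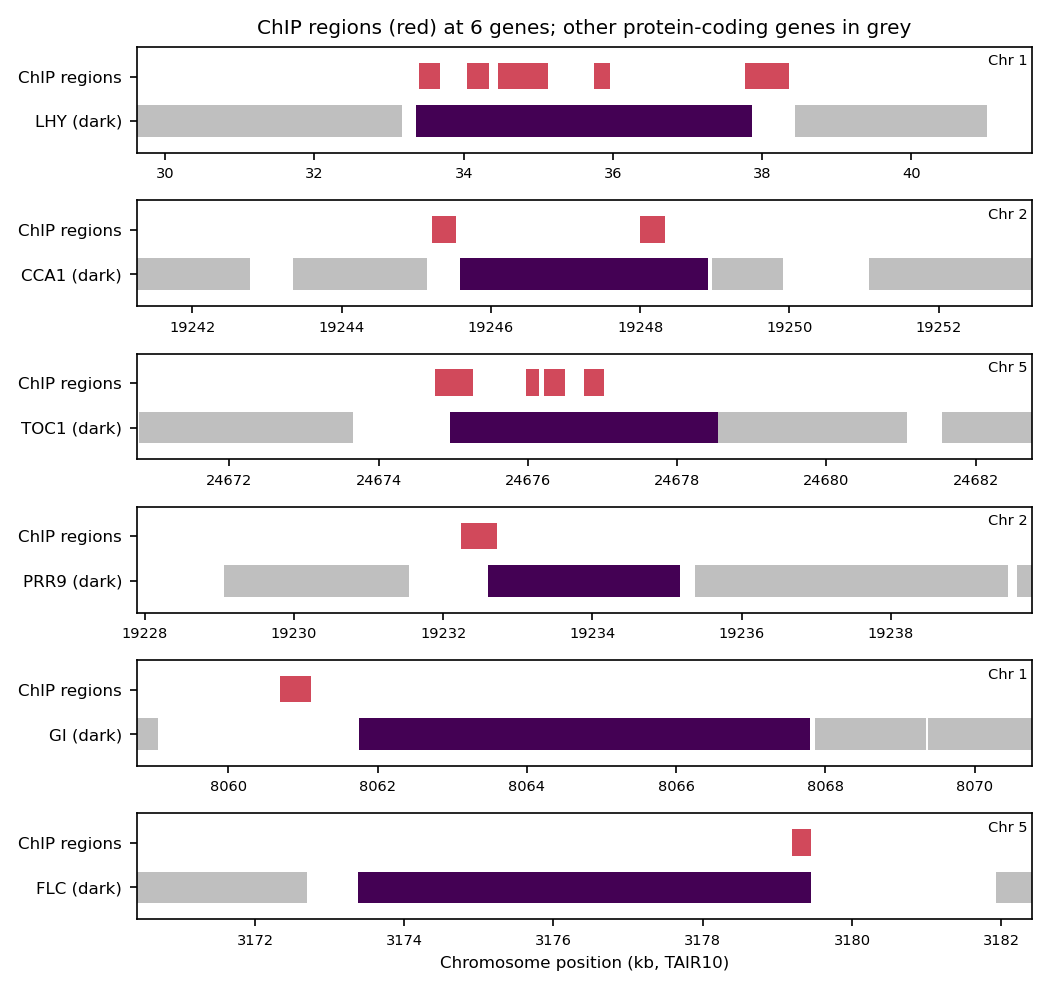
ChIP regions (red, upper track) and protein-coding genes (lower track, named gene dark, others grey) in windows centred on LHY, CCA1, TOC1, PRR9, GI and FLC, with chromosome position in kb on the horizontal axis. Regions overlap LHY, CCA1, TOC1, PRR9 and FLC, and the region at GI lies 640 bp outside the gene.

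Flowering-time genes held a region in 7 of 35 cases (20%, ratio 1.64, Fisher's exact adjusted p = 0.35), which did not differ detectably from other genes. The FLC gene, the MADS-box repressor of flowering, was overlapped by a region of 265 bp (chromosome 5: 3179193 to 3179457). FRI, an activator of FLC, lay 376 bp from a region of 614 bp that overlapped the body of another protein-coding gene. TEM1, TEM2, SMZ and SNZ, repressors of flowering from the RAV and AP2 families, each held a region, of 324, 245, 213 and 398 bp, as did SPL5 (284 bp). No region lay within 1 kb of FT, the mobile flowering signal, or of the integrator SOC1. The nearest lay 18809 bp from FT and 11541 bp from SOC1. The nearest region to the FLC relatives MAF4 and MAF5 was 29881 and 23464 bp away, and to the imprinted gene FWA 2839 bp away.

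Genes of stress, jasmonate and ethylene responses also held regions more often than other genes: 9 of 27 members (33.3%, 95% interval 16.5 to 54.0%), a ratio of 2.74 (Fisher's exact adjusted p = 0.0195). They were the jasmonate signalling repressors JAZ1, JAZ2, JAZ3 and JAZ6, the ethylene signal transducer EIN2 with 3 regions (widest 419 bp), the cold-response factor CBF1, the defence regulator WRKY40 (2 regions, widest 395 bp), the drought-response factor DREB2A (371 bp) and the heat-stress factor HSFA2. Of the 9, EIN2 and WRKY40 lie in the outer 1 Mb, 0.79 and 0.043 Mb from a chromosome end, and the others lie farther in. Only 4 of the 9 were overlapped, and for 7 of the 9 the region also lay within 1 kb of another protein-coding gene. At DREB2A and HSFA2, which lay beside their regions, the region overlapped the body of that neighbour. The list did not pass with gene bodies alone (ratio 1.93, adjusted Fisher's exact p = 0.328) or with regions of at least the median width (ratio 2.62, adjusted Fisher's exact p = 0.349, the highest of 9 alternatives, the lowest being 0.00912).

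**Figure D5:**
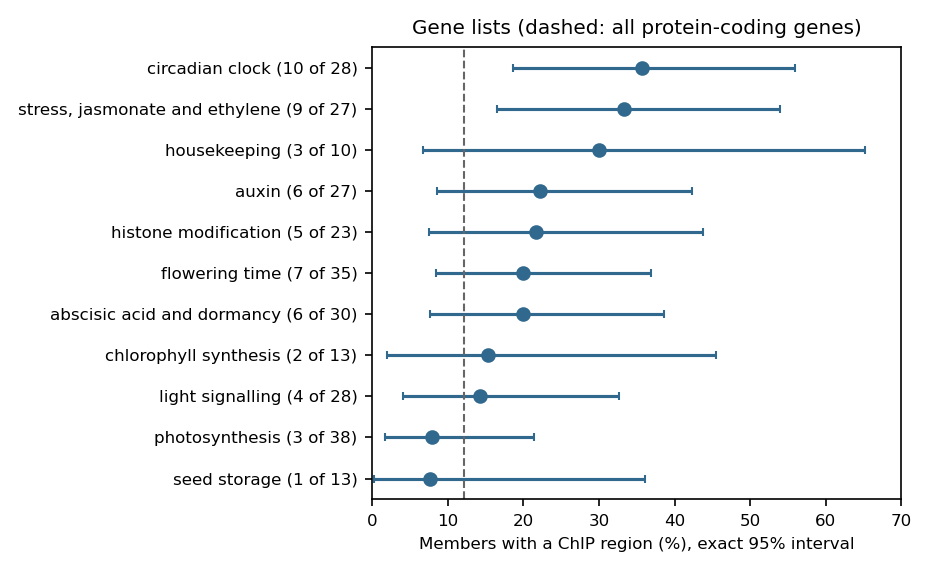
Percent of the members of each of 11 gene lists with a ChIP region within 1 kb (points) with exact 95% intervals (bars), and the share of all protein-coding genes, 12.2%, as a dashed line. The circadian clock (35.7%) and the stress, jasmonate and ethylene list (33.3%) have intervals that lie wholly above the line.

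The other 8 lists did not differ detectably from other genes, with adjusted Fisher's exact p from 0.35 to 1. Among 27 auxin genes, 6 were overlapped by a region: the efflux carriers PIN2, PIN3 and PIN4, the last with 5 regions, the receptors TIR1 (466 bp) and AFB2, and the response factor ARF19. Of these, PIN4 and TIR1 lie in the outer 1 Mb, 0.182 and 0.185 Mb from a chromosome end, and the others lie farther in. Among 30 genes of abscisic acid and dormancy, 6 held a region: the transcription factors ABI5 and ABF3, the kinase SNRK2.3 (435 bp), the biosynthetic genes NCED6 and ABA1, and the dormancy regulator DOG1. In the light-signalling list, 4 of 28 did: the photoreceptors PHYB and PHOT2, the transcription factor HY5 and RUP2. Photosynthesis genes held a region in 3 of 38 cases (7.89%: LHCB4.1, FNR1 and PSBO1, whose region contains a tRNA gene). All 3 lie in the outer 1 Mb, 0.21, 0.523 and 0.406 Mb from a chromosome end. Chlorophyll synthesis genes held a region in 2 of 13 cases (CHLH and CHLM), housekeeping genes in 3 of 10 (ACT7, UBQ10 and GAPC1) and seed storage genes in 1 of 13 (SESA1).

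Among 23 genes of histone modification, 5 held a region: LDL1 itself, the Polycomb-associated genes LHP1 and EMF1, the histone demethylase gene ELF6 and MSI5. The LDL1 region was unlike the others, at 3099 bp (chromosome 1: 23264575 to 23267673), and it covered 96.7% of the gene. The transgene carries the same LDL1 sequence, so reads from it and from the endogenous gene cannot be separated here.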

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

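The input intervals also covered the organelle genomes, which no comparison in the report used. The chloroplast genome was covered in 1 interval over 100% of its length (154478 bp). The mitochondrial genome was covered over 99.4% in 144 intervals, the widest of 48048 bp. These shares were singled out because they lie in sequence outside the comparisons and above what no reads would give. No ChIP region lay on either organelle, and whether organelle sequence was searched for regions is not given in the sources used here. No explanation was tested for these values.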

How the results depend on the processing

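Of 134 comparisons of a direction and test with an alternative, 115 kept both the direction and the side of the threshold. Many of the 115 concern gene lists that passed in neither setting, so this tally does not measure how well the passing results held. Of 15 comparisons of a count, 10 stayed within 1.5 times, which says nothing about the test of that count. Midpoints at either gene end, regions off tRNA, snRNA and rRNA genes, the arms alone, the nearest-gene assignment, whole coverage by input and the matching on position were chosen after seeing the data. Except where a value shows it, the cause was not tested. With regions of at least the median width, input overlap was still 100% but no longer past the threshold (permutation p = 0.104), genes with a region numbered 1552, and 1 list passed, the clock, at a ratio of 6.35. The stress, jasmonate and ethylene ratio of 2.62 no longer passed, chlorophyll synthesis turned to 0 and seed storage to 1.36. With gene bodies alone, 2108 genes held a region and 0 lists passed Fisher's exact test after adjustment, against 2 in the report, while 3 had an unadjusted p under 0.05 (clock, auxin and housekeeping). Ratios were then 2.79 for the clock and 1.93 for the stress list, both short of the threshold, with 2.90 for auxin and 3.91 for housekeeping. Photosynthesis and seed storage turned to 1.03 and 1.001. With each region given to its nearest gene, chlorophyll synthesis turned to 0.931, and 6 lists had an unadjusted p under 0.05 while 2 passed after adjustment. Without regions on a tRNA, snRNA or rRNA gene, the clock ratio was 2.46, short of the threshold, and 1 list passed, with fewer clock genes counted (8 of 28).

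Placement within the same 1 Mb left 26.1% of midpoints within 1 kb of a protein-coding gene, now above the placements, and 31.2% elsewhere, no longer past the threshold. It moved the ratio of genes with a region to 0.987, not past the threshold. With both changes, the arms alone and placement within the same 1 Mb, the class within 1 kb rose above the placements at 54.9%, the class elsewhere fell below them at 6.202%, and the gene ratio turned to 1.03. The arms were not tried with placement on the same chromosome, so their part in these moves was not separated. Non-coding RNA genes passed the threshold in the arms with placement within the same 1 Mb (1.08%), with gene bodies taking precedence (2.41%) and with every overlapped class counted (5.33%). Regions without input overlap could not be examined apart, because 0 regions lacked an input read and 1 was covered over less than 50% of its length. The motif alternatives were not run, and midpoints near the gene start were replaced by either gene end, since sequence and strand were not used here. No paired analysis was possible because the ChIP group has a single region set. For the same reason neither replicate could be left out.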

Other observations

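The comparisons of RNA genes and of gene coverage, the patterns of the gene-poor bins and chromosome ends, and the tests of the chromosome 2 block, of the ribosomal DNA ends, of depth as the whole cause, of strong transcription and of regions on tRNA, snRNA or rRNA genes, were chosen after the results were seen. Genes for tRNAs and spliceosomal snRNAs held regions well beyond their share. In the chromosome arms, 69 of 593 tRNA genes (11.6%) were overlapped by an LDL1:GFP region, against 6.12 ± 2.54 in placements within the same 1 Mb (SD, 1000 placements), a ratio of 11.3. Genes for spliceosomal snRNAs were overlapped in 18 of 81 cases (22.2%), a ratio of 15.5 (adjusted permutation p = 0.0045 for both). U2 entries made up 13 of the 18, and none of the entries named U6 held a region. The gene table lists several snRNA names at more than 1 position, so these are table entries rather than distinct genes. Long non-coding RNA genes were overlapped in 144 of 3146 cases, a ratio of 1.96 (adjusted permutation p = 0.0045). By contrast, 1 of 277 snoRNA genes was overlapped, against 3.20 ± 2.32 in placements (adjusted permutation p = 0.584). Members of the tRNA and snRNA families are often near-identical in sequence, so a read is not assigned to a single copy with certainty.

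In the arms, 1821 of 25876 protein-coding genes (7.04%) were overlapped by a region, against 1733 ± 24.7 in placements, and among those of at least 1 kb the median share of the gene covered was 8.81%. Of 22004 arm genes of at least 1 kb, 13 were covered over at least 80%. They included LDL1 (96.7%), the DELLA repressor of gibberellin responses RGL1 (81.6%), the cytochrome P450 gene CYP86A2 (80.3%), UNE11 (81.5%), and AT5G39180 (93.8%) and AT5G39150 (86.3%), which lie close together on chromosome 5. Another 6 lay in the first 100 kb of chromosome 2. On chromosome 4, AT4G00040 (89.3%), UNE11 and CYP86A2 lay near the upper end, starting at 14627, 32748 and 160643 bp. Both of these chromosome ends carry ribosomal DNA. The region at UNE11 also contains a tRNA gene, AT4G00085.

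The concentration of regions in gene-poor bins was not the work of the chromosome 2 block with mitochondrial sequence alone. Without the bin that holds it, these bins still held 2.97 times as many regions as placements. Whether sequence present in more copies in the plants than in the reference plays a part was not decided. Inside these regions 0.835% of bases had no input read, against 2.35% ± 0.124 in placements, but regions need aligned reads and placements do not, and regions in the arms showed a like shift (0.557% against 1.19% ± 0.063). No biological explanation was tested, since the design has no group without LDL1:GFP.

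The higher share of genes with a region near the chromosome ends may owe something to depth or to how well sequence aligns, because bases without an input read were fewer there (outer minus inner -0.305 percentage points over 10 arms, exact paired permutation p = 0.00195). Among genes with like local input coverage, however, outer genes still held a region 3.596 times as often as inner genes, with 3.001 to 4.61 over 10 classes of coverage. This argues against the share of bases with an input read as the whole cause. That share is a coarse stand-in for depth, so differences in depth within a class stay open. The ribosomal DNA at the upper ends of chromosomes 2 and 4 does not account for the pattern, as the lowest ratio among the other 8 arms was 2.38. Uneven recovery in the ChIP libraries stays open, and no biological explanation was tested.

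For the clock genes, the values argued against gene length alone and distance from the chromosome end alone: 0.1% of 10000 gene sets matched on length and 0.28% of sets matched on distance from the chromosome end held as many genes with a region. Length and distance were matched separately, not together. Of the clock genes with a region, LHY, CCA1, PRR9 and PRR7 lie 0.036, 0.451, 0.464 and 0.64 Mb from an end, and the others lie farther in. Closeness to an end therefore stays open as a part of the pattern. Strong transcription in general predicts at least as many regions at photosynthesis genes, where the share was 7.89% against 35.7% for the clock (Fisher's exact p = 0.0102). Photosynthesis genes are also shorter (median 1507.5 against 3121.5 bp) and lie farther from the chromosome end (median 5.28 against 3.51 Mb), though 6 members of each list lie within 1 Mb of an end. Gene sets matched on length held a region at 11.3% of genes for photosynthesis and 12.8% for the clock. For sets matched on distance the shares were 13.5% and 14.4%, so neither trait alone predicts a large gap. The test itself adjusts for neither trait and transcription was not measured, so this comparison cannot decide the question. Housekeeping genes held a region at 3 of 10 (95% interval 6.67 to 65.2%), a ratio of 2.46 that did not pass. Their ratio was above that of the clock with gene bodies alone (3.91 against 2.79, adjusted Fisher's exact p = 0.132 for housekeeping). It was also above with nearest-gene assignment (3.63 against 3.47) and without regions on RNA genes (2.58 against 2.46). In the other alternatives it was below, as with regions of at least the median width (3.54 against 6.35) and in the arms (1.93 against 3.10). Constitutive transcription therefore stays open as a part of the pattern. That LDL1 is found at clock genes more often than at other genes may be kept only as a hypothesis. It is not particular to the clock, since the stress, jasmonate and ethylene list had a ratio of 2.74, against 2.93 for the clock. The clock call was lost with gene bodies alone and, at a ratio of 2.46, without regions on a tRNA, snRNA or rRNA gene, so tRNA genes beside PRR7 and GRP7 stay open as a part of the pattern. No plants without the GFP fusion were analysed here.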
